A study of Arabidopsis thaliana with 4 samples.

How the data were processed

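RNA of whole Arabidopsis thaliana seedlings (Columbia-0), 14 days old, was measured on 4 2-colour Agilent arrays. Per the labels, each array held 1 biological replicate of seedlings carrying 35S:AtERF4-HA in one channel and seedlings carrying 35S:NLS-GFP-HA, the control, in the other. Both genotypes of a replicate grew on the same agar plate with 0.5% sucrose, in 16 h light and 8 h dark at 23 degrees Celsius, and 1 µg of total RNA was labelled per channel. The AtERF4-HA RNA carried Cy3 on arrays 1 and 2 and Cy5 on arrays 3 and 4, so 2 arrays had each dye orientation. All 4 arrays lay on 1 slide and came from 1 scan per the file headers, so slide and scan could not be tested as batches.

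The authors' deposited scanner files give spot intensity in the green (Cy3) and red (Cy5) channels, made with Agilent Feature Extraction 9.1.3.1 per the submitters' processing notes and the file headers. The files hold median spot signals and local background, background-subtracted signals, processed signals that the scanner software had dye-normalized, and flags for spots well above background, saturated or uneven. The deposited log10 ratio in these files was, per the file headers, red over green. It lay within 0.001 of the log10 of the processed signals' quotient in 100% of 123397 spots compared. The authors' value table in the series matrix, 37478 probes by 4 arrays, turned out to hold natural log ratios. Its columns had slopes of 0.694, 0.697, -0.695 and -0.693 against the log2 of red over green, where the natural log of 2 is 0.693, and correlated with it at 0.99, 0.99, -1.00 and -1.00. Its columns were not centred on 0: their medians were -0.22, -0.05, -0.14 and -0.08. How the authors made that table is not given in the sources used here.

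The direction of every ratio was taken from the dyes in the labels, as AtERF4-HA over control. By the same dyes the authors' value table runs the other way on all 4 arrays, control over AtERF4-HA, although the titles put AtERF4-HA over control. Which of titles, dye labels and value table is right stays unknown, and each direction below is that of the dye labels. An exchange of the dye labels would turn every rise into a fall of the same size.

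Median signals were background-corrected with normexp (offset 50) on the median local background and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R. The design fixed before the data were examined had assumed mean spot signals. The files gave medians, which were used, so the planned exchange of mean for median signals was not run. Control spots and spots with outlier flags were left out, and spots of the same probe were averaged. Of 37478 probes, 26236 (70.0%) had an Arabidopsis gene identifier, for 25665 genes, of which 25449 were found by locus in the RefSeq gene table of assembly TAIR10.1. That table gave the symbols of genes outside the gene lists. List members carry the symbols written in their lists, which can differ from those of RefSeq. The array's genome build is not given in the sources used here, so no coordinates are printed. A probe was kept if well above background on all 4 arrays in the AtERF4-HA channel or on all 4 in the control channel. The brightest kept probe stood for its gene. Of 398 genes with 2 or more kept probes, 2 had probes past the threshold in opposite directions, none of them a named gene.

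Each gene's 4 log2 ratios were fitted with limma (lmFit, eBayes) to a genotype term and a dye term, which are orthogonal here. That left 2 residual degrees of freedom and a prior of 2.79. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and a further count took those with an absolute log2 ratio of at least 1. Errors given as ± are standard errors of this fit over 4 arrays. They are moderated by eBayes and taken after the dye term, so they do not show the whole spread over arrays. The ratios of LEA7 (error 0.29) ran from -6.51 to -3.15 over the arrays, and those of RD29B (error 0.09) from -2.04 to -0.37. 21 gene lists with 377 members were fixed before the data were examined. They were senescence, photosynthesis, class II ERF, activator ERF, ethylene jasmonate defence, salicylate defence, jasmonate, ethylene pathway, abscisic acid and cold, glucosinolate, iron, flavonoid, cell division, leaf shape regulators, root tissue, early stress, circadian clock, heat shock, auxin response, cell wall loosening and reference genes. Each was tested with camera at a preset inter-gene correlation of 0.01, ERF4 left out, and adjusted over the 21 lists, with an estimated correlation and fry as alternatives. No list passed with an estimated correlation (lowest adjusted p = 0.45). In that form camera takes its test on the 2 residual degrees of freedom, which leaves little power for any list. The root tissue list had an estimated correlation of -0.02, below the preset, yet its camera p went from 0.00068 to 0.069. A failure in that form therefore does not show that correlation between genes accounts for a shift.

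The genes named were set by a rule fixed beforehand. It took ERF4, the 12 largest rises and 12 largest falls past the threshold with the same sign on all 4 arrays, ESP and WRKY53, and all class II ERF members. From each other list it took up to 4 members past the threshold with the largest absolute log2 ratio, or, with none past, the 2 with the lowest p. On simulated arrays, 200 genes among 19492 were changed, and the 30 measured senescence members were lowered by 1 on the log2 scale. These arrays went through the same background correction, loess, fit and list tests, but not the spot flags, probe filter or choice of probe. Of the 200, 85.1% of changes of 0.5 on the log2 scale, 100% of changes of 1 and 100% of changes of 2 were recovered. There, 22 unchanged genes were called, 9.17% of all calls, with those of senescence members counted, and 1 of 20 unchanged lists passed. Noise was drawn independently for each gene, so this gives no error rate for lists whose members vary together. Its size came from the variances moderated by eBayes, which are less scattered than unmoderated ones. Far fewer genes were changed than the 4983 that passed in the real data. The recovered shares are therefore not the power of the real comparison. In the real data the estimated correlation within a list reached 0.86 (cell division), an estimate that itself rests on 2 residual degrees of freedom.

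Alternatives tried were no background correction, offset 16, the scanner software's processed signals, Aquantile after loess, median centring, no filter or a stricter filter on dim probes, the mean over probes, no dye term, array weights, each array left out, and the authors' value table. The share of promoters with a GCC box was planned but needs a genome sequence, which was not used here. Precision is limited by the number of arrays: a p-value rests on 4 of them.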

Results

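Transcript levels of seedlings overexpressing ERF4, an ethylene response factor of the class II repressors that carry an EAR motif, were compared with those of control seedlings expressing a nuclear green fluorescent protein. Both transgenes were driven by the 35S promoter and carried an HA tag. The title of the series places the comparison in the regulation of leaf senescence by class II ERF repressors. The 4 arrays formed 1 group of 4 biological replicates, each with both genotypes on the same array. Median spot signals were 122 to 140 in green and 166 to 222 in red, over median backgrounds of 58 to 60. Between 58.0% and 62.4% of gene probe spots were well above background in a channel, and after filtering 19492 genes were tested.

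ERF4 (AT3G15210) was higher in the channel labelled AtERF4-HA on all 4 arrays, by 0.93 ± 0.07 on the log2 scale (1.91-fold, n = 4 arrays, limma adjusted p = 0.0028). Its log2 ratios on arrays 1 to 4 were 0.98, 0.87, 0.82 and 1.04. The authors' deposited value table, read as the titles put it, has the opposite sign on all 4 arrays, with ERF4 at -0.87, -0.71, -0.75 and -0.85 on its natural log scale. Over all probes its columns correlated with the ratios by the labels at -0.66, -0.77, -0.50 and -0.78. ERF4 was read by a single probe whose position in the gene was not used here, so it is not known whether the probe reads the transgene, the endogenous gene or both. All directions below are those of the dye labels, and each sample is named by its label.

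Of 19492 genes tested, 4983 passed the threshold, 2654 higher and 2329 lower in the channel labelled AtERF4-HA. Among genes changed 2-fold or more the balance tipped to falls, with 184 higher and 538 lower. The largest fall was that of LEA7 (AT1G52690), a late embryogenesis abundant protein, at -4.90 ± 0.29 (29.9-fold lower). The largest rise was that of AT5G42530, at 3.33 ± 0.29 (10.1-fold higher). Falls outnumbered rises among all calls in some other settings. Without array 1, 681 genes passed, 255 higher and 426 lower (412 at 2-fold or more), and without array 2, 659, 227 higher and 432 lower (390). Without array 3, 3237 were higher and 3881 lower. Without array 1, 47 of 96 named genes with a value lost their call, and without array 2, 48. In both cases the spread between replicates is estimated from arrays 3 and 4 alone. With arrays 1 and 3 averaged and arrays 2 and 4 averaged, an alternative added after seeing the data, 2653 genes passed, 1266 higher and 1387 lower. With arrays 1 and 4 and arrays 2 and 3 averaged, also added, 7902 passed, 3939 higher and 3963 lower. No background correction gave 9120, 4195 higher and 4925 lower, background-subtracted signals, also added, 9234, 4251 higher and 4983 lower, the scanner software's processed signals 8972, 5047 higher and 3925 lower, and the authors' value table, turned to the labels' direction, 10955. Median centring in place of loess moved the split at 2-fold or more to 290 higher and 488 lower, the authors' value table to 839 and 1124, and that table's split of all calls was 7892 to 3063.

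Of the 12 largest falls past the threshold and alike on all 4 arrays, 4 were members of the senescence list. SEN4 (AT4G30270), a xyloglucan endotransglucosylase gene, fell, at -3.84 ± 0.16, SAG14 (AT5G20230), a blue copper-binding protein, at -3.63 ± 0.17, the dark-inducible beta-glucosidase BGLU30 (AT3G60140) at -3.57 ± 0.43, and SAG13 (AT2G29350), a short-chain dehydrogenase, at -3.40 ± 0.15. The lipid transfer protein gene LTP4 (AT5G59310) fell, at -4.16 ± 0.53, the glycine-rich protein gene GRP3S (AT2G05380) at -4.05 ± 0.06, AT2G18193 at -3.93 ± 0.30 and PS2 (AT1G73010), a phosphatase induced by phosphate starvation, at -3.76 ± 0.07. AT4G12490 fell, at -3.60 ± 0.61, the alternative oxidase AOX1D (AT1G32350) at -3.54 ± 0.53 and the cytochrome P450 CYP81D8 (AT4G37370) at -3.41 ± 0.30. In the AtERF4-HA channel AT4G12490 was well above background on 1 of 4 arrays and LTP4 on 3 of 4. Without array 1 or array 2, AT4G12490 and AOX1D did not pass (adjusted p = 0.080 to 0.11), nor did LTP4 without array 2 (0.064). With processed signals and with the authors' value table LTP4 came to -6.96 and -6.85, and AT4G12490 to -7.27 and -7.16.

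The other large rises included EXPA8 (AT2G40610), an expansin that loosens cell walls, at 2.58 ± 0.15, and the ammonium transporter AMT1;3 (AT3G24300) at 2.26 ± 0.20. ACD6 (AT4G14400), an ankyrin protein of salicylate-dependent defence, rose by 2.16 ± 0.27 and PCC1 (AT3G22231) by 2.35 ± 0.56. AT2G28780 rose by 2.49 ± 0.18, AT5G67430 by 2.39 ± 0.42, AT2G25510 rose 4.92-fold (SE 0.28 on the log2 scale) and AT1G51830 by 2.13 ± 0.12. AT2G47880 rose by 2.07 ± 0.43, ZIP7 (AT2G04032) by 2.05 ± 0.46 and AT4G16260 by 2.04 ± 0.30. Of these 12 rises, 7 did not pass without array 1 or without array 2 (adjusted p = 0.062 to 0.18): AT5G67430, PCC1, AT2G25510, ACD6, AT2G47880, ZIP7 and AT4G16260, nor did AMT1;3 without array 2 (0.052). PCC1, from 1.51 (without array 4) to 3.19 with an array left out, and ZIP7 did not pass with offset 16 either (0.057 and 0.060), nor did AT2G47880 and ZIP7 with arrays 1 and 3 and arrays 2 and 4 averaged (0.055 and 0.072). With processed signals and with the authors' value table AT5G67430 came to 4.71 and 4.82, AT2G47880 to 3.87 and 3.98, and ZIP7 to 4.52 and 4.63.

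**Figure D1:**
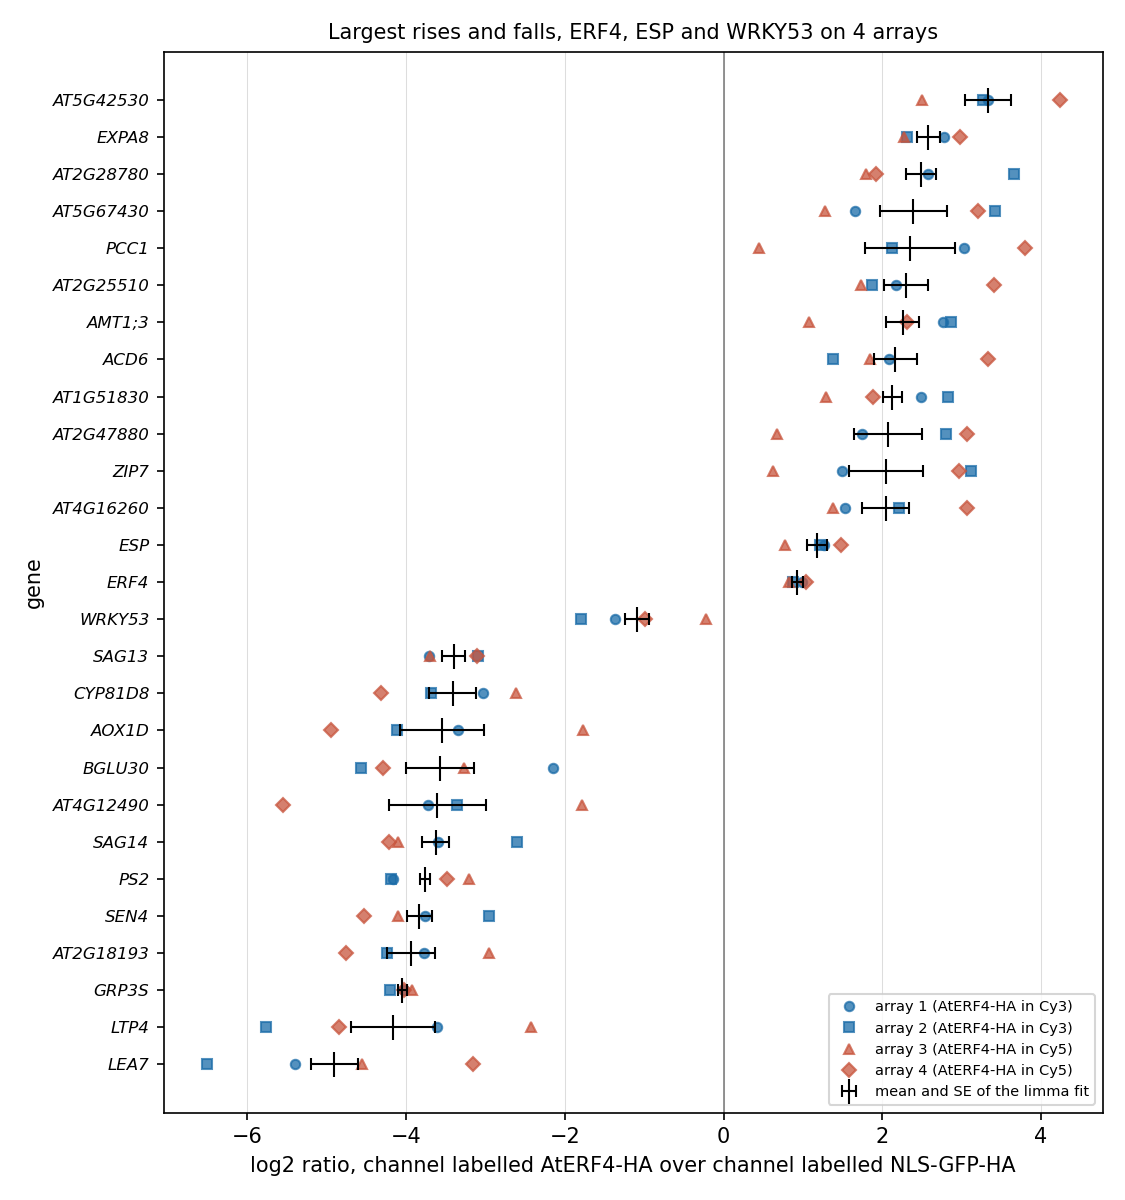
Log2 ratios of the channel labelled AtERF4-HA over the control channel (x axis) for the 12 largest rises, the 12 largest falls, ERF4, ESP and WRKY53 (y axis). Points are the 4 arrays, blue where AtERF4-HA carried Cy3 and red where it carried Cy5, and black bars the mean and SE of the limma fit, from -4.90 for LEA7 to 3.33 for AT5G42530.

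The senescence list, genes that rise in ageing leaves, was lower as a group, with a median log2 ratio of -1.02. Of 30 measured members 24 fell, 2 rose and 4 did not pass. Adjusted over the list alone, 26 fell and 2 rose. WRKY53 (AT4G23810), a transcription factor of early leaf senescence, fell, at -1.10 ± 0.15 (2.14-fold), and the NAC factor ORE1 (AT5G39610) fell, at -1.24 ± 0.10. The members that rose were the NAC factor NAP (AT1G69490), at 0.74 ± 0.09, and NOL (AT5G04900), a chlorophyll b reductase, at 0.24 ± 0.05. The list passed camera (adjusted p = 1.1e-10), but not with an estimated correlation (adjusted p = 0.45). SAG12 was well above background on too few arrays to be tested, and WRKY53 did not pass without array 1 (adjusted p = 0.066) or array 2 (0.088).

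Photosynthesis genes moved the other way, with a median of 0.59. By array the median was 0.32 and 0.41 on arrays 1 and 2, where AtERF4-HA carried Cy3, and 0.81 and 1.05 on arrays 3 and 4, where it carried Cy5. Of 35 measured members 29 rose, 1 fell and 5 did not pass, and adjusted over the list alone 31 rose and 1 fell. LHCA1 (AT3G54890), an antenna protein of photosystem I, rose by 1.03 ± 0.06 and PSBQ2 (AT4G05180), of the oxygen-evolving complex, by 1.03 ± 0.06. The antenna proteins LHCB4.2 (AT3G08940) and LHCB6 (AT1G15820) rose by 0.95 ± 0.06 and 0.86 ± 0.06. The photosynthesis list passed camera (adjusted p = 5.7e-13; adjusted p = 0.48 with an estimated correlation). Some members, such as the LHCB1 genes, have near-identical copies that probes may not separate.

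Among the class II ERF genes other than ERF4, 1 of 5 measured rose and none fell, also adjusted over the list alone. ERF8 (AT1G53170) rose by 0.36 ± 0.07 (adjusted p = 0.023), but did not pass without array 1 (0.14) or array 2 (0.12), or with arrays 1 and 3 and arrays 2 and 4 averaged (0.051). The values of the others did not pass: ERF9 (AT5G44210) was at 0.38 ± 0.12, ERF7 (AT3G20310) at 0.11 ± 0.05, ERF11 (AT1G28370) at -0.12 ± 0.10 and ERF3 (AT1G50640) at -0.16 ± 0.05. ERF10 (AT1G03800) was well above background on too few arrays, and ERF12 (AT1G28360) was well above background in neither channel. As a group the list did not pass (median 0.11, adjusted p = 0.54), with a median of 0.25 with median centring, 0.26 with the value table and -0.0050 without a filter on dim probes, and ERF9 passed without array 3 (0.015), without background correction (0.0015), with processed signals (0.0031), with median centring (0.018) and with the value table (0.0023). ERF3 passed as lower without background correction (-0.19, adjusted p = 0.031) and ERF7 as higher with the value table (0.26, adjusted p = 0.024). With alternatives added after seeing the data, ERF9 passed with background-subtracted signals (0.0021) and with arrays 1 and 4 and arrays 2 and 3 averaged (0.0058), and ERF3 with background-subtracted signals (0.038). With an array left out ERF9 ranged from 0.24 (without array 4) to 0.53 and ERF11 from -0.21 to -0.02, and with background alternatives ERF11 reached -0.29 (processed signals). ERF3 came to -0.01 and ERF7 to 0.25 with median centring, ERF3 to -0.02 with the value table, ERF8 to 0.54 with processed signals and 0.65 with the value table, and ERF9 to 0.96 and 1.08.

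The activator ERF list, 13 chosen ERF genes outside class II, was lower, with a median of -0.60. Of 12 measured, 6 fell, 1 rose and 5 did not pass, and adjusted over the list alone 8 fell and 1 rose. ERF1 (AT3G23240), an activator downstream of ethylene and jasmonate, fell, at -1.87 ± 0.34, ERF2 (AT5G47220) at -1.29 ± 0.07, ERF1A (AT4G17500) at -1.13 ± 0.09 and ERF104 (AT5G61600) at -0.90 ± 0.14. Without array 1 or array 2, ERF1 and ERF104 did not pass (adjusted p = 0.060 to 0.12), and ERF1 came to -3.47 with processed signals and -3.36 with the value table. The list passed camera (adjusted p = 0.0018; adjusted p = 0.45 with an estimated correlation), and its median was -1.02 with processed signals, -0.91 with the value table and -0.39 without a filter on dim probes. In the ethylene pathway list 2 of 19 genes fell and 17 did not pass, with the same counts adjusted over the list alone. The receptor gene ERS1 (AT2G40940) fell, at -0.41 ± 0.06 and EBF2 (AT5G25350), which targets EIN3 for degradation, at -0.40 ± 0.07. This list had a median of -0.13 (camera adjusted p = 0.020; adjusted p = 0.65 with an estimated correlation), and it did not pass without array 1 (adjusted p = 0.063) or with median centring (0.12). Its median was 0.0046 with median centring, -0.04 with the value table and -0.08 without array 4. ERS1 and EBF2 did not pass without array 1 or array 2 (adjusted p = 0.077 to 0.11).

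Jasmonate genes were lower as a group (median -0.40). Of 23 measured, 9 fell, 2 rose and 12 did not pass, and adjusted over the list alone 14 fell and 2 rose. The lipoxygenase LOX2 (AT3G45140) fell, at -2.14 ± 0.27, CORI3 (AT4G23600) at -1.24 ± 0.30, the repressor gene JAZ1 (AT1G19180) fell by 1.00 ± 0.07 and the allene oxide cyclase AOC2 (AT3G25770) at -0.87 ± 0.06. Jasmonate genes passed camera (adjusted p = 0.00018; adjusted p = 0.45 with an estimated correlation), with a median of -0.67 with processed signals. LOX2 and CORI3 did not pass without array 1 (adjusted p = 0.070 and 0.17) or array 2 (0.055 and 0.18). CORI3, from -1.69 to -0.78 (without array 3) with an array left out, did not pass with offset 16 (0.058) or with arrays 1 and 3 and arrays 2 and 4 averaged (0.060).

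Defence genes of the ethylene and jasmonate branch split. Of 8 measured, 3 fell, 2 rose and 3 did not pass, and adjusted over the list alone 5 fell and 2 rose. The defensin genes PDF1.4 (AT1G19610), PDF1.3 (AT2G26010) and PDF1.2c (AT5G44430) fell, at -3.04 ± 0.42, -1.93 ± 0.47 and -1.93 ± 0.45, while the basic chitinase CHI-B (AT3G12500) rose by 1.27 ± 0.20. The list did not pass (median -1.06, adjusted p = 0.22), except without array 4 (0.017), with median centring (1.2e-06), with the processed signals (0.034) and with the authors' value table (0.0072). Its median moved to -3.54 with processed signals, -3.43 with the value table, -1.84 without background correction, -0.60 without a filter on dim probes and -0.64 without array 4. PDF1.2c and PDF1.3 belong to near-identical copies that probes may not separate, and neither passed with offset 16 (adjusted p = 0.056 and 0.060). Without array 1 or array 2 none of PDF1.4, PDF1.3, PDF1.2c and CHI-B passed (adjusted p = 0.077 to 0.17). With an array left out PDF1.3 ranged from -2.62 to -1.24 and PDF1.2c from -2.59 to -1.27, both nearest to 0 without array 4, and with processed signals both came to -3.71, and to -3.59 and -3.60 with the value table.

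Salicylate defence genes also went both ways. Of 14 measured, 6 fell, 1 rose and 7 did not pass, and adjusted over the list alone 7 fell and 3 rose. The monooxygenase FMO1 (AT1G19250), of systemic acquired resistance, fell, at -2.83 ± 0.47, the glutaredoxin GRX480 (AT1G28480) at -2.56 ± 0.20 and EDS5 (AT4G39030), a transporter in salicylate synthesis, at -0.82 ± 0.16. WRKY70 (AT3G56400) rose by 0.89 ± 0.20, a call lost with offset 16 (adjusted p = 0.0505) and without array 1 (0.082), array 2 (0.18) or array 4 (0.0501), and with arrays 1 and 3 and arrays 2 and 4 averaged (0.076). FMO1 and EDS5 did not pass without array 1 or array 2 (adjusted p = 0.093 to 0.13), and FMO1 came to -4.59 with processed signals and -4.47 with the value table. The list did not pass (median -0.36, adjusted p = 0.099), but did without array 2 (0.016), array 3 (0.037) or array 4 (0.036), with median centring (0.00037) and with the authors' value table (0.021). Its median was -0.15 without a filter on dim probes.

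Genes induced within minutes by touch, wounding or elicitors, listed as early stress, were lower (median -0.69). Of 19 measured, 13 fell, 2 rose and 4 did not pass, and adjusted over the list alone 15 fell and 2 rose. The calmodulin-like gene TCH3 (AT2G41100) fell, at -2.43 ± 0.18, the zinc finger gene ZAT12 (AT5G59820) at -1.80 ± 0.13 and WRKY18 (AT4G31800) at -1.43 ± 0.11, while CBF3 (AT4G25480), a regulator of cold response, rose by 1.45 ± 0.10. This list passed camera (adjusted p = 8.4e-05; adjusted p = 0.45 with an estimated correlation). The heat shock list was lower too (median -0.41), with 4 of 10 measured genes lower and 6 not past, and 4 lower adjusted over the list alone. HSP23.5 (AT5G51440) fell, at -1.15 ± 0.19, HSP90.1 (AT5G52640) at -1.14 ± 0.08, HSP70 (AT3G12580) at -1.08 ± 0.12 and DREB2A (AT5G05410) at -0.36 ± 0.05. Its median was -0.95 with processed signals, -0.84 with the value table, -0.23 without a filter on dim probes and -0.25 without array 4. It passed camera (adjusted p = 0.0011; adjusted p = 0.48 with an estimated correlation), and DREB2A did not pass with median centring (adjusted p = 0.26) the authors' value table (0.051) or arrays 1 and 3 and arrays 2 and 4 averaged (0.0501). Without array 1 or array 2 HSP23.5, HSP70 and DREB2A did not pass (adjusted p = 0.058 to 0.12).

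Of the abscisic acid and cold list, 7 of 19 measured genes rose, 5 fell and 7 did not pass, with 8 higher and 6 lower adjusted over the list alone. The cold-responsive genes COR15B (AT2G42530), COR15A (AT2G42540) and RD29A (AT5G52310) rose by 1.31 ± 0.07, 1.12 ± 0.08 and 1.13 ± 0.09, and RD29B (AT5G52300), induced by dehydration through abscisic acid, fell, at -1.22 ± 0.09. RD29B came to -2.05 without background correction, -3.01 with processed signals, -2.89 with the value table and -2.14 with background-subtracted signals. These genes as a list did not pass (median 0.18, adjusted p = 0.36), with a median of 0.34 with median centring, 0.30 with the value table and 0.11 without array 4. In the glucosinolate list 5 of 31 measured genes rose, 6 fell and 20 did not pass, with 6 higher and 8 lower adjusted over the list alone. ESP (AT1G54040), which steers glucosinolate breakdown towards nitriles and epithionitriles, rose by 1.18 ± 0.12 (2.27-fold, adjusted p = 0.0061), and the myrosinase TGG2 (AT5G25980) by 0.92 ± 0.12. The nitrile specifier NSP5 (AT5G48180) fell, at -1.46 ± 0.09 and CYP79B3 (AT2G22330), of indole glucosinolate synthesis, at -0.61 ± 0.09. ESP did not pass without array 1 (adjusted p = 0.062) or array 2 (0.063), nor did CYP79B3 (0.076 and 0.11), nor TGG2 without array 2 (0.056). As a group the genes did not pass (median -0.09, adjusted p = 0.46), and the direction turned with median centring (0.69) and without array 1 (0.88). Their median was 0.09 with median centring, 0.06 with the value table, -0.06 with processed signals, -0.06 without array 4 and -0.0066 without array 1.

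Auxin response genes were higher (median 0.88), with 8 of 14 measured genes higher, 1 lower and 5 not past, and 11 higher and 1 lower adjusted over the list alone. SAUR22 (AT5G18050), SAUR23 (AT5G18060) and SAUR24 (AT5G18080) rose by 1.31 ± 0.10, 1.25 ± 0.09 and 1.02 ± 0.14, and GH3.3 (AT2G23170), which conjugates auxin to amino acids, fell, at -2.60 ± 0.39. The list passed camera (adjusted p = 0.0014; adjusted p = 0.48 with an estimated correlation), though 6 of the 8 genes that rose are the neighbouring SAUR19 to SAUR24, near-identical copies. SAUR24 and GH3.3 did not pass without array 1 or array 2 (adjusted p = 0.078 to 0.10), and SAUR24 came to 1.63 with the value table. Root markers were higher as well (median 0.47), with 6 of 13 measured genes higher, 1 lower and 6 not past, and 9 higher and 1 lower adjusted over the list alone. The phosphate transporter PHT1-1 (AT5G43350) rose by 1.41 ± 0.11, the aquaporins TIP2-3 (AT5G47450) and TIP2-2 (AT4G17340) by 1.18 ± 0.09 and 0.72 ± 0.13, and CASP1 (AT2G36100), of the Casparian strip, by 0.47 ± 0.08. This list passed camera (adjusted p = 0.0018; adjusted p = 0.45 with an estimated correlation). TIP2-2 and CASP1 did not pass without array 1 or array 2 (adjusted p = 0.070 to 0.13), nor did TIP2-2 with arrays 1 and 3 and arrays 2 and 4 averaged (0.056). The list median was 0.74 with processed signals and 0.85 with the value table.

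Of the cell division list, 2 of 14 measured genes rose and 12 did not pass, and none passed adjusted over the list alone. The cyclin genes CYCB1-4 (AT2G26760) and CYCD3-1 (AT4G34160) rose by 0.46 ± 0.11 and 0.44 ± 0.10. The list passed camera (median 0.26, adjusted p = 0.0092; adjusted p = 0.65 with an estimated correlation) but not without array 2 (0.055) or with the authors' value table (0.056), and its median was 0.17 without array 2, 0.56 with processed signals and 0.68 with the value table. CYCB1-4 did not pass with offset 16 (adjusted p = 0.052), without a dye term (0.052) or without array 3 (0.054), and neither cyclin gene passed without array 1 or array 2 (0.070 to 0.19). With processed signals CYCB1-4 came to 0.70, and with the value table to 0.81. Leaf shape regulators split into 5 higher, 1 lower and 11 not past of 17 measured, with 6 higher and 1 lower adjusted over the list alone. SHY2 (AT1G04240), an auxin repressor, rose by 1.25 ± 0.05 and the leaf growth regulators TCP2 (AT4G18390) and TCP4 (AT3G15030) by 0.65 ± 0.06 and 0.58 ± 0.06, while NAC1 (AT1G56010) fell, at -0.69 ± 0.08. The list did not pass (adjusted p = 0.44), and its median of -0.03 differed in sign from its mean of 0.11 and the test. TCP2 and TCP4 did not pass without array 1 or array 2 (adjusted p = 0.052 to 0.070), nor did NAC1 without array 1 (0.059). The list median ranged from -0.08 without background correction to 0.08 with the value table, and was also above 0 with median centring, with the stricter filter and without array 1 or array 4.

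The cell wall loosening list had 7 members above and 7 below 0, with 5 of 14 measured genes higher, 3 lower and 6 not past, and 5 higher and 4 lower adjusted over the list alone. Beside EXPA8, the expansin EXPA5 (AT3G29030) rose by 1.15 ± 0.07, while XTH18 (AT4G30280) and the expansin EXPA10 (AT1G26770) fell, at -1.15 ± 0.12 and -0.92 ± 0.07. This list did not pass (adjusted p = 0.82), its median of -0.10 differed in sign from its mean of 0.11 and the test, and the test turned with processed signals (0.69), with the value table (0.33) and without array 3 (0.84). Its median ranged from -0.33 with the stricter filter to 0.08 with the value table. Of the iron list, 2 of 16 measured genes rose, 3 fell and 11 did not pass, with the same counts adjusted over the list alone. The iron storage ferritins FER1 (AT5G01600) and FER4 (AT2G40300) fell, at -1.89 ± 0.07 and -0.81 ± 0.07, and FRO2 (AT1G01580), the root ferric reductase, and BHLH101 (AT5G04150) rose by 0.95 ± 0.20 and 0.61 ± 0.08. Iron genes as a list did not pass (median -0.03, adjusted p = 0.57), with a median from -0.12 without array 3 to 0.17 with the value table, above 0 also with processed signals, with median centring and without array 4. FRO2 and BHLH101 did not pass without array 1 or array 2 (adjusted p = 0.069 to 0.14), nor did FER4 without array 1 (0.056). In the flavonoid list 2 of 16 measured genes fell and 14 did not pass, also adjusted over the list alone. PAP1 (AT1G56650), a MYB activator of anthocyanin synthesis, fell, at -1.48 ± 0.07 and PAL1 (AT2G37040), the entry enzyme of phenylpropanoid synthesis, at -0.60 ± 0.06. This list passed camera (median -0.29, adjusted p = 0.015; adjusted p = 0.65 with an estimated correlation), but not without array 4 (0.29) or without background correction (0.062), and PAL1 did not pass without array 1 (0.057) or array 2 (0.063). The flavonoid median was -0.05, -0.16, -0.02 and -0.77 on arrays 1 to 4, -0.06 without array 4, -0.52 without array 3, -0.17 with median centring and -0.14 with the value table.

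The clock and reference lists served as markers of the hour of harvest and of scaling. Of 12 clock genes, 2 fell and 10 did not pass, also adjusted over the list alone. LUX (AT3G46640) fell, at -0.39 ± 0.08 and ELF3 (AT2G25930) at -0.39 ± 0.09, and the list did not pass (median -0.02, adjusted p = 0.50), with a median from -0.07 without background correction to 0.08 with median centring and with the value table. Of 10 reference genes, 1 rose, 2 fell and 7 did not pass, also adjusted over the list alone. GAPC1 (AT3G04120) fell, at -0.44 ± 0.05, ACT2 (AT3G18780) at -0.34 ± 0.06 and SAND (AT2G28390) rose by 0.20 ± 0.05, and the list did not pass (median -0.08, adjusted p = 0.48), turning with median centring (0.90), where its median was 0.11, and lowest with processed signals, at -0.15. Median centring shifted the median of all genes to 0.11, from 0.01, and the value table to 0.16. With median centring none of LUX, ELF3, GAPC1, ACT2, SAND, ERS1 and EBF2 passed, and GAPC1 came to -0.26, ACT2 to -0.12 and SAND to 0.32 (0.34 with the value table). SAND also did not pass with offset 16 (adjusted p = 0.059), without a dye term (0.052), without array 3 (0.067) or without array 4 (0.11), EBF2 without a dye term (0.069) and ELF3 without array 4 (0.063). Without array 1 or array 2 none of LUX, ELF3, GAPC1, ACT2 and SAND passed (adjusted p = 0.079 to 0.26). With arrays 1 and 3 and arrays 2 and 4 averaged LUX, ELF3, ACT2 and SAND did not pass (0.053 to 0.14), nor did SAND with background-subtracted signals (0.051).

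**Figure D2:**
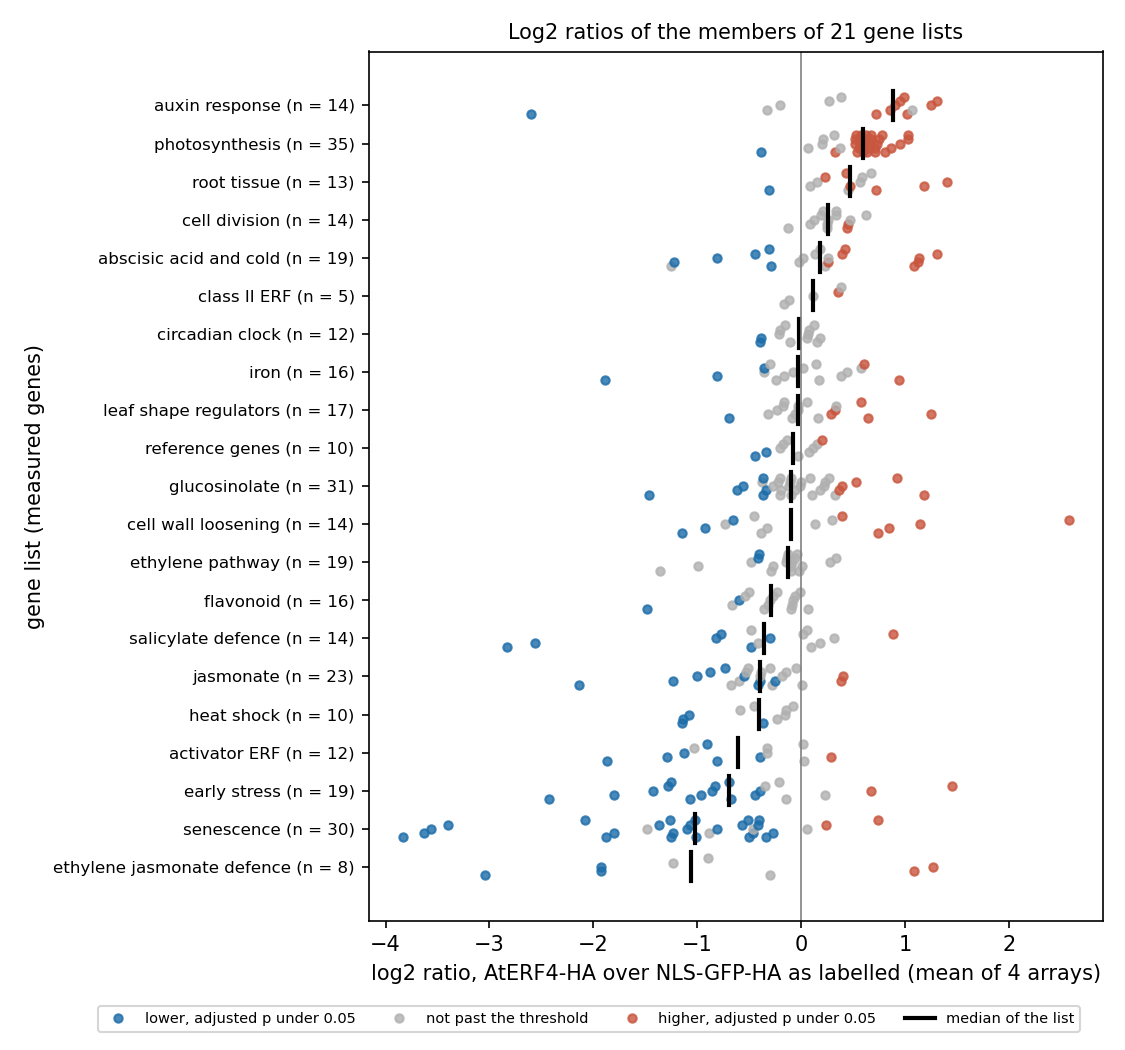
Log2 ratios (x axis, mean of 4 arrays) of the measured members of the 21 gene lists (y axis), each point a gene and each black bar the list's median. Colours show genes past the threshold, and medians range from -1.06 for ethylene jasmonate defence to 0.88 for auxin response.

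Oriented log2 ratios of the arrays correlated at 0.87 (arrays 1 and 2) and 0.75 (arrays 3 and 4) within a dye orientation, and at 0.70 to 0.80 between orientations. With each gene's dye effect taken out, the correlations were 0.95 (arrays 2 and 4), 0.89 (1 and 3), 0.89 (1 and 4) and 0.84 (2 and 3) between orientations, and 0.85 (1 and 2) and 0.74 (3 and 4) within. Taking it out gives both orientations the same mean for each gene, which by construction draws arrays of different orientations together. These are correlations across 19492 genes, which are not independent replicates.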

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

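The tests of explanations in this part were all chosen after the results they bear on were seen. Of 118 values examined for an array far from the other 3, 4 stood out, 3.39% where chance gives about 1 in 20. TCH3 was less far below 0 on array 3 (-1.61) than on the others (-2.66, -2.77 and -2.67), a gap of 0.899 of the whole range. CBF3 was lower on array 3 (1.04) than on the others (1.57, 1.63 and 1.57), a gap of 0.897. SAUR22 was higher on array 1 (1.66) than on the others (1.16, 1.19 and 1.24), a gap of 0.830. The class II ERF median was higher on array 4 (0.33) than on the others (0.02, 0.06 and 0.06), a gap of 0.871. Each value was examined on its own, so a difference that many values share on 1 array need not stand out. Of the 12 largest rises, all but ACD6 were nearest 0 on array 3. Of the 12 largest falls, so were all but LEA7, SEN4, SAG14, BGLU30 and SAG13. Among the list medians the exceptions were photosynthesis, class II ERF, jasmonate, cell division, heat shock and reference genes. The cause was not tested.

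Signal above background also lay in probes that the comparisons leave out. Of 11242 probes without a gene identifier, most placed by chromosome position only, 1852 (16.5%) were well above background on all 4 arrays in a genotype's channel, against 0 of 153 negative control spots. Fitted in the same way but adjusted as a set of their own, 13 of the 1852 were higher and 8 lower past the threshold (limma). Of the genes tested, 25.6% passed, in another fit and another adjustment, so these shares do not measure a difference in response.

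The value table and the dye labels give opposite directions. The explanation that the dye labels were exchanged on all 4 arrays predicts a lower ERF4 signal in the channel labelled AtERF4-HA, if the probe reads the transgene, and ERF4 was higher there by 0.93 on the log2 scale. That rise ranked 238 among 19492 genes, so it is not of a size that only a transgene would give, and a probe outside the transgene would say nothing. The explanation that the value table holds control over AtERF4-HA needs negative correlations with the ratios by the labels, and the highest of the 4 was -0.50, as an exchange of labels would also give. The pair of explanations cannot be told apart, because the position of the ERF4 probe was not known. A direction turned for all genes would make the senescence, jasmonate and early stress lists higher, and the photosynthesis list lower, in AtERF4-HA seedlings.

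The senescence list was lower, with a median of -1.02. Probe-specific dye bias would give opposite signs in the dye orientations, whereas the list medians were -0.99 and -0.86. Another hour of harvest would move morning and evening clock genes apart, and their medians differed by 0.18, at -0.02 and -0.20 (4 and 5 genes). The size that would count as a move was set after the results were seen. How far clock genes would move for a given fall of the senescence list is not known here, so a small difference in hour is not excluded. These tests do not close the list of causes. The transgene itself, the difference that the design names, and a difference in developmental age between the lines stay open. The early stress list (median -0.69) and the 19 phosphate starvation genes tested below (median -1.46) were lower too. Both genotypes of a replicate grew on the same plate and so shared its medium. Other differences in handling or nutrition between the channels were not tested. The direction of each fall rests on the dye labels.

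Under the 7 sign patterns of the 4 arrays that the dye term allows, only that of the labels, 1 pattern, gave as many genes past the threshold (4983, highest other 0). These are too few patterns for a share under 0.05.

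Photosynthesis and root markers were both higher. More shoot tissue in the channel labelled AtERF4-HA would lower root markers, whose median was 0.47, with 12 of 13 above 0. More root tissue would lower photosynthesis genes, whose median was 0.59, with 34 of 35 above 0. A changed share of shoot and root alone therefore leaves 1 of the lists unaccounted for. The transgene, the developmental age of the lines and other causes stay open, untested.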

How the results depend on the processing

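The alternatives with background-subtracted signals and with averaged arrays were chosen after seeing the data. Of 92 named genes past the threshold besides ERF4, all 92 kept their direction under the alternatives chosen beforehand that were run. Each had the same sign on all 4 arrays, so leaving out an array always keeps its direction and does not test it. The fits without a dye term and with array weights gave the list medians of the main setting (senescence -1.02 in each). Directions kept in these fits therefore add nothing. The call was kept by 77 of the 92 under alternatives that did not leave out an array, and by 42 whichever array was left out. Without array 1, 47 of 96 named genes lost the call, and without array 2, 48. With any array left out the spread rests on 1 degree of freedom, from the complete dye orientation, and the lone array of the other is assumed to vary like them. Of the 92, 91 kept the call with background-subtracted signals, 81 with arrays 1 and 3 and arrays 2 and 4 averaged, and 92 with arrays 1 and 4 and arrays 2 and 3 averaged. ERF4 passed under each of these alternatives, with an adjusted p of 0.041 without array 1, 0.039 without array 2 and 0.011 with arrays 1 and 3 and arrays 2 and 4 averaged. Aquantile after loess leaves ratios as they are and so tests nothing.

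Genes past the threshold numbered 659 to 7118 with an array left out, 9120 without background correction, 8972 with processed signals, 10955 with the value table and 9234 with background-subtracted signals. With arrays 1 and 3 averaged and arrays 2 and 4 averaged, as if each pair were a dye swap of the same extracts, 2653 passed, and with arrays 1 and 4 and arrays 2 and 3 averaged, 7902. Genes changed 2-fold or more numbered 390 to 1051, 1133, 1889, 1963 and 1191 in the first 5 of these settings. The median correlation of arrays moved to 0.84 without background correction, 0.84 with processed signals, 0.84 with the value table and 0.59 with median centring.

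Lists are given by adjusted p. The test with an estimated correlation rests on 2 residual degrees of freedom and had little power for any list. With an estimated correlation senescence, activator ERF, jasmonate, root tissue and early stress came to 0.45, photosynthesis, heat shock and auxin response to 0.48, and ethylene pathway, flavonoid and cell division to 0.65. With fry the ethylene pathway (0.16), flavonoid (0.21), cell division (0.22) and heat shock (0.068) lists did not pass. Flavonoid did not pass without background correction (0.062). With processed signals ethylene jasmonate defence passed (0.034) and cell wall loosening turned (0.69). With median centring ethylene jasmonate defence (1.2e-06) and salicylate defence (0.00037) passed, the ethylene pathway did not (0.12), and glucosinolate (0.69) and reference genes (0.90) turned. With the value table ethylene jasmonate defence (0.0072) and salicylate defence (0.021) passed, cell division did not (0.056) and cell wall loosening turned (0.33). With an array left out the range was 0.017 to 0.36 for ethylene jasmonate defence, 0.016 to 0.35 for salicylate defence, 0.0088 to 0.063 for ethylene pathway and 0.092 to 0.88 for glucosinolate. It was 6.8e-05 to 0.29 for flavonoid, 0.00012 to 0.055 for cell division and 0.77 to 0.91 for cell wall loosening. The cause of these changes was not tested, beyond the fewer arrays. Not run were the GCC box in promoters, which needs a genome, the slide as a block, with 1 slide and 1 scan, and median in place of mean signals, since medians were the main setting. Signal over background limits dim genes: 121 genes tested were dim in the AtERF4-HA channel on all 4 arrays and 43 in the control channel.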

Other observations

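The test of phosphate starvation genes and the averaging of arrays were chosen after results here were seen. Genes of the phosphate starvation response were lower in the channel labelled AtERF4-HA. Beside PS2, named above, the acid phosphatase PAP17 (AT3G17790) fell, at -2.90 ± 0.06 and SRG3 (AT3G02040) at -2.87 ± 0.08, as did AT5G20790 at -2.93 ± 0.13 and PAP14 (AT2G46880) at -1.76 ± 0.43, which led to the hypothesis that phosphate starvation genes fell as a group. Without these genes and PHT1-1, a list of 19 further genes of this response was written before their values were looked at. All 19 were measured: 15 fell, none rose and 4 did not pass, with a median of -1.46 and 17 of 19 below 0 (camera p = 4.1e-10, p = 0.17 with an estimated correlation, fry p = 0.0075). The regulator SPX1 (AT5G20150) fell, at -2.60 ± 0.06, the galactolipid synthase MGD3 (AT2G11810) at -2.61 ± 0.20, the sulfolipid synthesis genes SQD1 (AT4G33030) and SQD2 (AT5G01220) at -1.84 ± 0.12 and -1.46 ± 0.10, and the ribonuclease RNS1 (AT2G02990) at -2.61 ± 0.36. In the AtERF4-HA channel RNS1 was well above background on 3 of 4 arrays. The phosphate transporter PHT1-4 (AT2G38940) fell, at -0.98 ± 0.12, unlike PHT1-1, which rose. The direction rests on the dye labels.

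Of further transporter genes, picked after their values were seen and not tested as a group, the nitrate transporter NRT1.1 (AT1G12110) rose by 1.78 ± 0.09 and the sulfate transporter SULTR1;2 (AT1G78000) by 1.61 ± 0.07. The nitrate transporter NRT2.1 (AT1G08090), at 0.57 ± 0.19, and the iron transporters IRT1 (AT4G19690), at 0.38 ± 0.17, and IRT2 (AT4G19680), at 0.57 ± 0.22, did not pass (limma adjusted p = 0.089, 0.16 and 0.11). The potassium transporter HAK5 (AT4G13420), well above background in the control channel on 0 of 4 arrays, did not pass either (adjusted p = 0.11).

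Over 19492 genes, the difference of array 2 from array 1 correlated with that of array 4 from array 3 (Pearson r = 0.39, Spearman rho = 0.35). These are correlations across genes, which are not independent replicates. With arrays 1 and 3 averaged and arrays 2 and 4 averaged, 2653 genes passed the threshold, and with arrays 1 and 4 and arrays 2 and 3 averaged, 7902. The labels call the 4 arrays separate biological replicates, and no cause was tested. If arrays 1 and 3, and arrays 2 and 4, were dye swaps of the same extracts, n would be 2. The p-values of the main fit, which take n as 4, would then be too low.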
